A study of Sus scrofa with 6 samples.

How the data were processed

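Single pig oocytes at the germinal vesicle stage, 3 BCB-negative and 3 BCB-positive, were profiled by RNA sequencing, with a single oocyte in each library. Per the labels' protocols, oocytes came from antral follicles 3 to 6 mm wide, with at least 3 cumulus layers, and were stripped of cumulus cells and zona pellucida before lysis. cDNA was primed with poly(dT) of 24 nt and amplified by PCR, and the libraries shared a lane of an Illumina sequencer. The protocol names no molecular identifiers, so reads are not independent molecules, and any counting interval or floor covers counting error only.

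The submitters' processing notes name BWA, Cufflinks, RSEM and the pig genome build Sscrofa10.2; the role, order and versions of these tools are not given in the sources used here. The deposited files gave, for each gene and each transcript, a length, an expected count and an FPKM (fragments scaled to transcript length and to mapped fragments). Expected counts in the deposited files are estimates that split reads among transcripts and need not be whole. FPKM values in the deposited files were normalised by the authors for length and depth and rounded to 2 decimals. For genes with ample counts, the length implied by FPKM was 53.0 to 73.1 bases shorter than the listed length, by the median in each oocyte. The files listed features with counts above 0, and a gene missing from an oocyte's file was set to 0.

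Genes carried NCBI gene IDs. Symbols were taken from a table of the pig assembly Sscrofa11.1, used for names and for which genes neighbour or overlap each other, with no coordinates reported. Of 19300 genes, 13936 matched by gene ID and 1 by transcript accession. The remaining 5363 held between 8.65% and 10.2% of the counts in an oocyte and stayed in all counts of genes. A symbol that was not a placeholder was found for 12189 genes. Among genes compared, 78 had values identical to another gene's in all oocytes, as happens when reads are divided between copies.

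The measure was the BCB-positive minus BCB-negative difference of the mean log2(FPKM + 1), over the 11493 genes with a mean of at least 1 FPKM in the 6 oocytes. Differences on this scale understate those of low genes. The labels name no animal, donor or culture for any oocyte, and each library is 1 cell. Each class was therefore treated as 1 sample made of 3 cells, and no p-value, standard error or test between classes was computed. The SD given beside a difference is the pooled SD between oocytes of a class on the log2 scale. A gene was described as ordered where all 3 oocytes of a class lay above all 3 of the other. Chance orders 5% of genes in each direction and 10% in either. Genes that were ordered and at least 2-fold apart on the log2(FPKM + 1) scale were counted.

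Before the data were examined, 21 gene lists and 5 lists of markers of other cell types were fixed. For each gene list the median difference was computed, along with the number of members that were ordered and at least 1.5-fold apart. Chance orders 5% of members in each direction, before the limit on size. The percentile of the median among 10000 random lists of the same size, matched in 20 bins of mean expression, describes these libraries and is not a test. The list of 13 mitochondrially encoded genes had no matched member and was not analysed here. The named genes followed a rule fixed at the same time. It took the 12 ordered genes with a symbol and the largest difference in each direction among those with at least 5 FPKM in the higher class, and up to 4 ordered members of each list, or 2 members where none was ordered. It also took the 2 most abundant genes of each marker list, the 5 most abundant genes overall and 5 genes with the largest ordered isoform shifts. Some genes under this rule are not reported here. Isoform shares were computed for 1956 genes with 2 or more listed transcripts and at least 5 FPKM in every oocyte, and were counted where ordered and at least 20 percentage points apart.

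Alternatives fixed in advance were another pseudocount, scaling by median-of-ratios size factors or to a common sum, the ratio of class means, CPM from the counts, other filters on low values, Spearman correlation and leaving out each oocyte in turn. List counts without BCB-positive oocyte 3, removal of a trend on gene length and the sum of overlapping genes PYURF and PIGY were added after seeing the data. A gene ordered with all oocytes stays ordered when any is left out. A member said to keep the rule without an oocyte therefore passed anew on size alone. The ordering rule was tested on simulated counts for the 11493 genes of the comparison of BCB-positive with BCB-negative oocytes. It recovered 46.0% of 100 genes simulated at 2-fold and 97.0% of 100 genes simulated at 4-fold, with 0 in the wrong direction. Of 11293 unchanged genes, 131 met the rule. Each simulated gene had the median SD of its expression bin and noise independent of other genes. The most variable genes and effects shared across a library were therefore absent from the simulation. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.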

Results

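Brilliant cresyl blue (BCB) is a dye that some oocytes reduce to a colourless form. Oocytes that lose the colour, here BCB-negative, are generally taken as still growing, and oocytes that keep it, here BCB-positive, as fully grown. The transcriptomes of 3 BCB-negative and 3 BCB-positive pig oocytes at the germinal vesicle stage were compared, each library being a single oocyte. Expected counts summed to 7620913, 7668881 and 7122749 in BCB-negative oocytes 1, 2 and 3, and to 7820374, 8192732 and 9238987 in BCB-positive oocytes 1, 2 and 3. Genes with at least 1 FPKM numbered 11157, 10729 and 10819 in the BCB-negative oocytes and 11068, 10994 and 11751 in the BCB-positive oocytes. The class means differed by 369 genes, and by 129 without BCB-positive oocyte 3. With no animal or culture named for any oocyte, each class stood as 1 sample of 3 cells, and differences were described without a test.

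The transcriptomes did not separate by BCB class. Across genes, which are not independent replicates, the Pearson correlation of log2(FPKM + 1) averaged 0.904 over the 6 pairs within a class and 0.902 over the 9 pairs between classes. The library that stood apart was BCB-positive oocyte 3, whose mean correlation with the other oocytes was 0.874, against 0.905 to 0.915 for the rest. Without it the means were 0.917 within and 0.918 between classes. Its 10 most abundant genes held 9.80% of its counts, against 15.6% to 19.0% in the other oocytes.

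**Figure D1:**
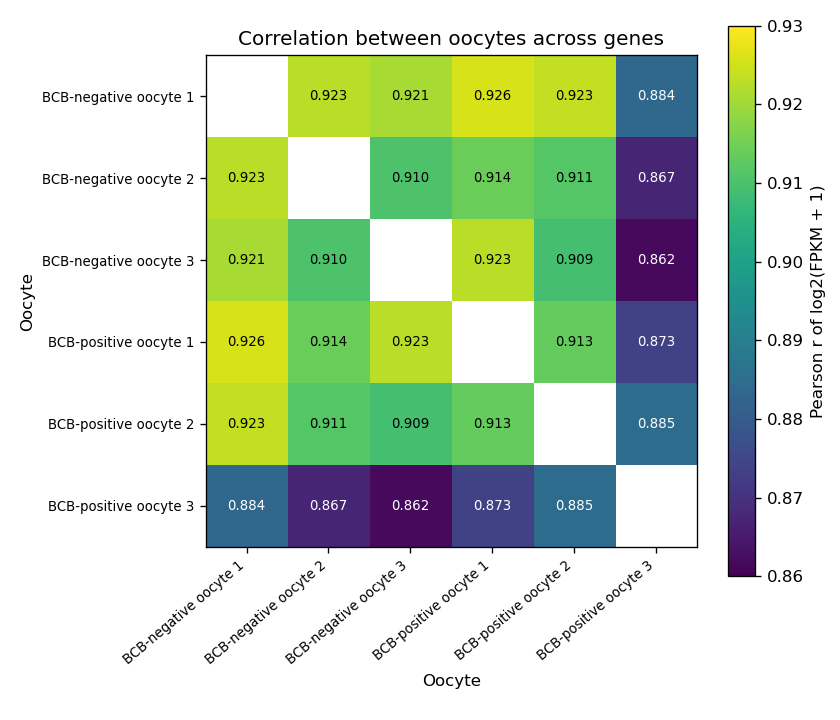
Pearson correlation of log2(FPKM + 1) across genes for each of the 15 pairs of oocytes, with both axes listing the oocytes and colour giving r. The pairs with BCB-positive oocyte 3 lie between 0.862 and 0.885.

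The pentose phosphate pathway, which makes NADPH and ribose, did not separate the classes. Of its 10 measured genes, 1 was ordered and at least 1.5-fold higher and 0 were lower. That gene was RPIA, ribose-5-phosphate isomerase, at 28.0, 21.7 and 36.5 FPKM in BCB-negative oocytes and 37.4, 67.8 and 65.2 FPKM in BCB-positive oocytes. The median difference of the pathway was 0.00, at percentile 25.9 of matched random lists. It was -0.09 under size factor scaling, 0.09 with FPKM rescaled to a common sum, -0.14 at percentile 8.67 without BCB-positive oocyte 3 and -0.16 without BCB-positive oocyte 2.

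Among 11493 genes, SPATA22, a gene of meiotic recombination, had the largest ordered difference towards BCB-positive oocytes. SPATA22 was at 1.67, 0 and 0.41 FPKM in BCB-negative oocytes and at 9.65, 15.1 and 14.2 FPKM in BCB-positive oocytes, a log2 difference of 3.14 (SD 0.56). RGS10, a regulator of G protein signalling, was 0 in the BCB-negative oocytes and stood at 2.97, 9.32 and 4.16 FPKM in the BCB-positive oocytes. SKA2, a component of the spindle and kinetochore complex, averaged 4.42 FPKM in BCB-negative and 20.3 FPKM in BCB-positive oocytes, with a log2 difference of 1.93 (SD 0.42). The cyclophilin PPIL3, the ubiquitin ligase RNF13 and the lysosomal thioesterase PPT1 had log2 differences of 2.49, 2.30 and 2.20. ZNF382, UTP3, CD302, SSMEM1, ZCWPW2 and FAM184A differed by 2.33, 2.24, 2.16, 2.15, 2.15 and 1.88. Without BCB-positive oocyte 3 the same genes differed by 1.66, 1.85, 2.06, 1.87, 2.13 and 1.26. PPIL3, RNF13 and PPT1 then differed by 2.17, 2.21 and 1.55. CD302 was narrowly ordered, at 5.84 FPKM in BCB-negative oocyte 1 and 6.54 FPKM in BCB-positive oocyte 1. ZNF382 (SD 1.07) was at 1.08, 6.52 and 15.0 FPKM in BCB-positive oocytes and at most 0.47 FPKM in BCB-negative oocytes. PPIL3 overlaps NIF3L1 and RNF13 overlaps PFN2 in the reference annotation, so their values are uncertain.

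In the other direction, SNRPD3, a core protein of the spliceosome, was at 440, 398 and 287 FPKM in BCB-negative oocytes and at 58.1, 41.1 and 158 FPKM in BCB-positive oocytes. Its log2 difference was -2.33 (SD 0.74). MGMT, which repairs alkylated guanine in DNA, averaged 451 FPKM in BCB-negative and 186 FPKM in BCB-positive oocytes. Its difference was -1.55 with all oocytes and -0.87 without BCB-positive oocyte 3. The axonemal genes CCDC40 and RSPH9 differed by -1.65 and -1.45, the nucleoside diphosphate kinase NME1 by -1.61, and HAPLN2 by -2.32. NME1 rested on 87 counts in BCB-negative and 22 in BCB-positive oocytes. The neighbouring gene NME2 stood at 107 to 220.5 FPKM. Whether reads were divided between NME1 and NME2 was not tested, so NME1 is uncertain. STPG4 and PLP2 differed by -1.45 and -1.55, and MCMDC2, a relative of the replicative helicase subunits, by -1.68 (SD 1.12). MCMDC2 was narrowly ordered, at 7.41 FPKM in BCB-positive oocyte 3 and 8.25 FPKM in BCB-negative oocyte 3. PLEKHG5 differed by -2.13 (SD 1.59), and by -0.91 without BCB-positive oocyte 3. It was narrowly ordered, at 21.5 FPKM in BCB-positive oocyte 2 and 23.0 FPKM in BCB-negative oocyte 1. PYURF had the largest difference, -5.40 (SD 3.00), but was also near 0 in BCB-negative oocyte 3, at 0.46 FPKM. PYURF overlaps PIGY, and the sum of both differed by 0.31. PLP2 overlaps PRICKLE3, which was at most 0.73 FPKM, and their sum stayed ordered at -1.55, so the overlap leaves a lesser doubt. AVPR1A, at -1.73, had values identical to those of gene 100737663, so it is uncertain.

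**Figure D2:**
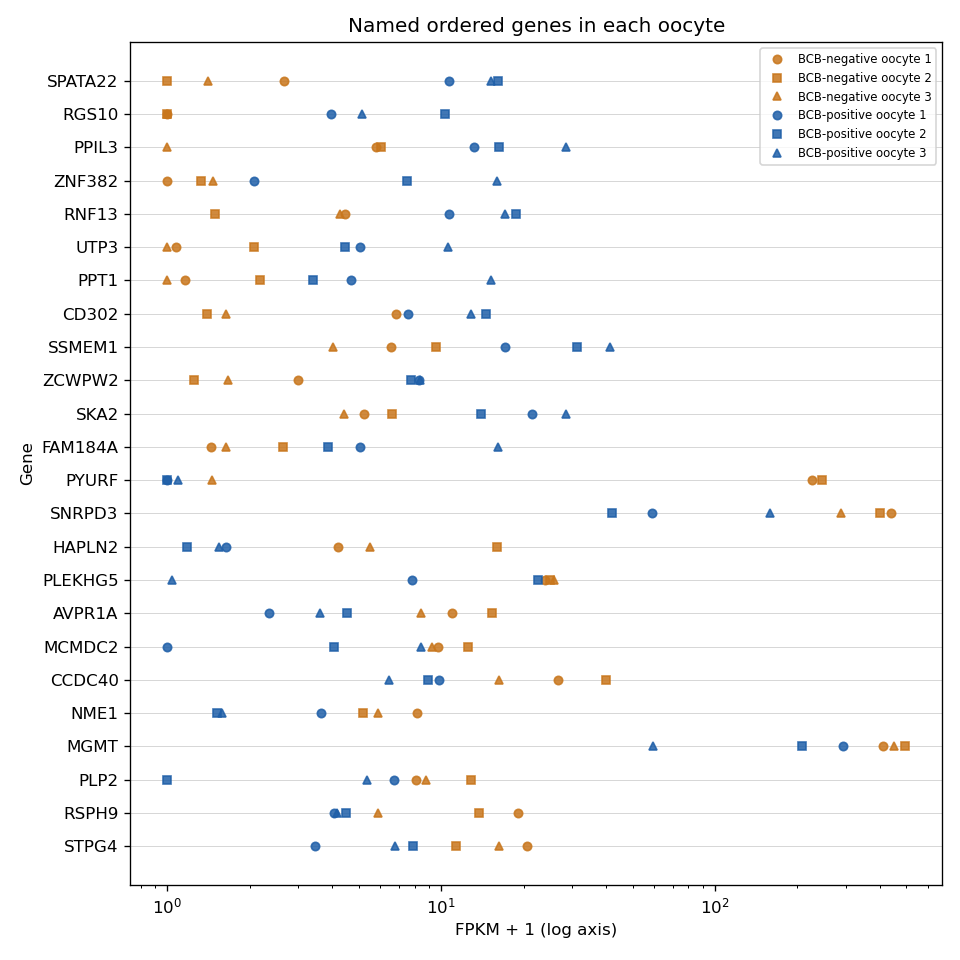
FPKM plus 1, on a log axis, of the named genes with the largest ordered differences, with a point for each oocyte, coloured by BCB class. BCB-negative oocyte 3 lies near the BCB-positive oocytes for PYURF.

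More genes were ordered towards BCB-positive oocytes than the other way. All 3 BCB-positive oocytes lay above all 3 BCB-negative oocytes for 855 genes, or 7.44%, and below them for 463 genes, or 4.03%. Chance gives 5% in each direction and 10% in either on average. Genes of a library share effects, so a share can lie off 5% without a class difference. How far it can was not computed, so no excess over chance is claimed. Of the ordered genes, 329 were at least 2-fold higher and 128 at least 2-fold lower. Of 11293 genes simulated without a difference, 131 met that rule in either direction. The simulation gave each gene the median SD of genes of like expression and independent noise. It held neither the most variable genes nor a library that stood apart, so 131 is no bound on chance here. The observed counts were 258 and 159 under size factor scaling, 468 and 109 with FPKM rescaled to a common sum and 444 and 163 with a pseudocount of 0.1 FPKM. Without BCB-positive oocyte 3 they were 360 and 243, with fewer oocytes to order. Leaving out any other oocyte instead gave 488 to 861 higher and 237 to 321 lower genes. Part of the excess of higher genes thus went with BCB-positive oocyte 3. The median difference of all genes was 0.11 as deposited, 0.02 under size factors and 0.19 with FPKM rescaled to a common sum. The median SD between oocytes was 0.54, and 71.7% of genes differed by less than 1.5-fold.

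The medians of the spindle, meiosis and proteasome lists lay above 0 mainly through BCB-positive oocyte 3, while 4 spindle genes stayed 1.5-fold higher without it. Of 34 measured genes of the spindle, cohesin and checkpoint list, 4 were ordered and at least 1.5-fold higher and 0 lower. Chance orders 1.7 of 34 genes each way at any size. NDC80, a kinetochore protein, was at 25.3, 33.0 and 37.4 FPKM in BCB-negative and at 47.4, 54.7 and 161 FPKM in BCB-positive oocytes. RAD21 of cohesin, SGO1, which protects cohesin, and MAD2L1 of the spindle checkpoint differed by 1.34, 1.18 and 0.81. Without BCB-positive oocyte 3 all 4 stayed at least 1.5-fold higher, with RAD21 at 1.03, SGO1 at 1.01, MAD2L1 at 0.69 and NDC80 at 0.68. Leaving out an oocyte cannot undo their order, so only the size could fail. Without that oocyte 2 other members met the rule as lower. MAD2L1 was at 164, 164 and 50.5 FPKM in BCB-negative and at 176, 184 and 228 FPKM in BCB-positive oocytes. Much of its difference thus came from BCB-negative oocyte 3. SGO1 was also lowest there, at 3.70 FPKM against 9.99 and 9.83 FPKM in the other BCB-negative oocytes, so part of its difference did too. The list's median difference was 0.35, at percentile 99.2 of matched random lists, and -0.06 at percentile 11.1 without BCB-positive oocyte 3. Among 34 genes of meiotic arrest and resumption, 2 were higher and 0 lower, where chance again orders 1.7 each way at any size. CCNB2, a cyclin of the kinase that drives meiotic resumption, was at 97.1, 114 and 120 FPKM in BCB-negative and at 159, 157 and 377 FPKM in BCB-positive oocytes. CCNB3 differed by 0.95. CCNB2 and CCNB3 differed by 0.52 and 0.54 without BCB-positive oocyte 3, and 0 of the 2 kept the rule. FZR1 and CDC20, activators of the anaphase-promoting complex, differed by -0.56 and -0.44. The median was 0.24 at percentile 97.3, and 0.03 at percentile 48.1 without that oocyte. For the proteasome, 1 of 33 members was higher, PSMA4 by 0.99 and by 0.71 without that oocyte, and 0 were lower. The deubiquitinase UCHL1 differed by -0.54. The proteasome median was 0.29 at percentile 99.3, and 0.02 at percentile 44.7 without that oocyte.

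The medians of the ribosomal protein and respiratory chain lists lay below 0, again through BCB-positive oocyte 3. Of 73 ribosomal protein genes, 5 were ordered and at least 1.5-fold lower and 0 higher. Chance orders 3.65 of 73 genes each way at any size. RPL8 averaged 1130 and 712 FPKM, a log2 difference of -0.66 (SD 0.20), and -0.64 without BCB-positive oocyte 3. RPL27A and RPL31 differed by -0.90 and -0.79, and by -0.42 and -0.36 without it. The list's median was -0.31 at percentile 0.03, and 0.01 at percentile 50.8 without that oocyte, where 1 member was lower. Among 41 genes of the nuclear-encoded respiratory chain, 0 were ordered in either direction. NDUFS6 and NDUFS1, subunits of complex I, overlapped between classes at -1.63 (SD 1.21) and 1.08 (SD 0.82). The median was -0.25, smaller than the SD between oocytes of 0.28, at percentile 0.74, and -0.03 at percentile 18.8 without that oocyte. Of 16 genes of mitochondrial maintenance and dynamics, 2 were higher and 0 lower, OPA1 of inner membrane fusion by 1.16 and VDAC1, a channel of the outer membrane, by 0.70. OPA1 and VDAC1 differed by 0.56 and 0.38 without BCB-positive oocyte 3, and 0 members then met the rule. The list's median was 0.25 at percentile 87.7, and 0.02 without that oocyte.

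**Figure D3:**
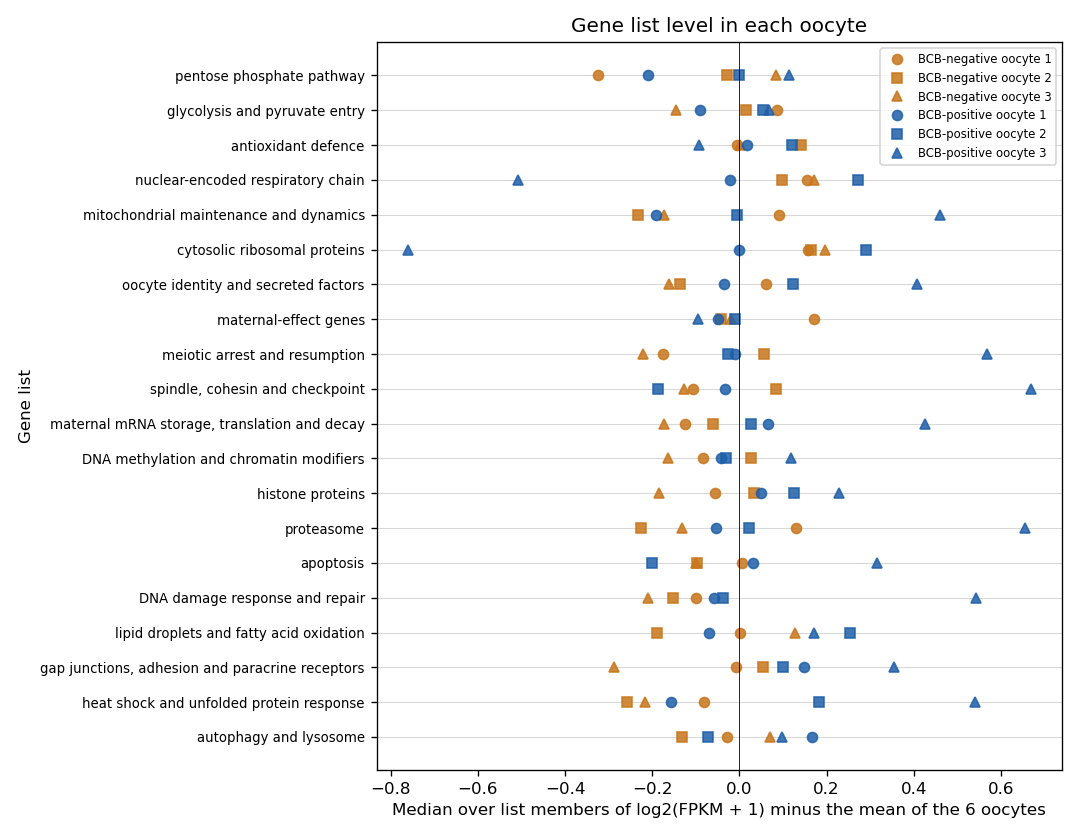
Median over the members of each gene list of log2(FPKM + 1) minus the mean of the 6 oocytes, with a point for each oocyte, coloured by BCB class. BCB-positive oocyte 3 lies at -0.76 for ribosomal proteins, 0.67 for the spindle list and 0.65 for the proteasome.

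In energy metabolism, LDHA, lactate dehydrogenase, was at 40.6, 29.8 and 36.6 FPKM in BCB-negative oocytes and at 62.8, 45.7 and 692 FPKM in BCB-positive oocytes. Its log2 difference was 1.81, and 0.58 without BCB-positive oocyte 3, where it no longer met the 1.5-fold rule. Of 16 measured genes of glycolysis and pyruvate entry, 1 was ordered and at least 1.5-fold higher, LDHA, and 1 was lower, the phosphofructokinase PFKL by -0.70. PDHA1 of pyruvate dehydrogenase and GPI, which makes fructose 6-phosphate, differed by -0.46 and -0.43. The list's median was 0.15 at percentile 59.8, 0.02 at percentile 37.2 without BCB-positive oocyte 3 and -0.01 without BCB-negative oocyte 1. Of 22 antioxidant genes, 1 was higher and 1 lower. Thioredoxin reductase TXNRD1 averaged 13.9 FPKM in BCB-negative and 21.5 FPKM in BCB-positive oocytes, and mitochondrial thioredoxin TXN2 203 and 128 FPKM. TXN2 differed by -0.57 without BCB-positive oocyte 3 and no longer met the rule. The median was 0.04 at percentile 44.8, and -0.06 under size factors. Of 25 genes of lipid droplets and fatty acid oxidation, 1 was higher and 0 lower. That gene was PPARG, a nuclear receptor of lipid metabolism, which averaged 30.9 and 65.2 FPKM and differed by 0.92, and by 0.48 without BCB-positive oocyte 3, where 0 lipid genes met the rule. The acyltransferase DGAT1 and the desaturase SCD differed by -0.50 and 0.42, and by -0.21 and 0.52 without that oocyte. The median was 0.10 at percentile 51.3.

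Of 18 genes of oocyte identity, 3 were higher and 0 lower, where chance orders 0.9 each way at any size. MAEL and TDRD1, which act in transposon silencing, and the receptor KIT differed by 0.84, 0.67 and 0.89. TDRD1 differed by 0.46 without BCB-positive oocyte 3, where 2 of the 3 kept the rule. MAEL was at 145, 111 and 130 FPKM in BCB-negative and at 195, 214 and 288 FPKM in BCB-positive oocytes. The median of this list was 0.20 at percentile 93.7, 0.14 at percentile 89.2 without BCB-positive oocyte 3, 0.11 without BCB-negative oocyte 3 and 0.37 without BCB-negative oocyte 1. Of 25 maternal-effect genes, 0 were higher and 0 lower by 1.5-fold. TLE6, of the subcortical maternal complex, differed by -0.53, FLOT2 by -0.41 and SIN3A by 0.35, and by 0.14 without BCB-positive oocyte 3. The median was -0.19 at percentile 5.54, and -0.05 without that oocyte. Of 37 genes of maternal mRNA storage, translation and decay, 7 were higher and 1 lower, where chance orders 1.85 each way at any size. The higher genes included the decay factor ZFP36L1 at 1.32 and the RNA-binding protein IGF2BP3 at 1.00. They also included the deadenylase subunit CNOT8 at 1.00 and the polyadenylation element binding protein CPEB2 at 0.98. The lower gene, named after its values were seen, was PABPC1L, a poly(A) binding protein, at -0.83. Without BCB-positive oocyte 3, 5 of the 7 kept the rule, IGF2BP3 differed by 0.54 and PABPC1L no longer met it. The median was 0.24 at percentile 95.3 with it and 0.09 at percentile 71.3 without it.

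Of 34 DNA methylation and chromatin modifiers, 0 were 1.5-fold higher and 0 lower, with a median of 0.14 at percentile 56.2. This median was 0.02 at percentile 34.9 without BCB-positive oocyte 3, and -0.04 with a trend on gene length removed. KMT2A, a histone methyltransferase, differed by -0.30 and TET3, which oxidises methylcytosine, by 0.16. Of 28 histone and histone chaperone genes, 11 were in the files and 10 were compared, so this list is far from complete. By 1.5-fold 0 were higher and 0 lower, and CHAF1A differed by -0.28. The class mean was higher for 8 of the 10, and the median was 0.18 (SD between oocytes 0.10) at percentile 81.5. Of 38 genes of DNA damage and repair, 3 were higher and 1 lower, where chance orders 1.9 each way at any size. The ligase cofactor XRCC4, the germline guardian TP63 and the kinase CHEK1 differed by 1.44, 0.78 and 0.63, and the ligase LIG1 by -0.71. Without BCB-positive oocyte 3 the 3 kept the rule, LIG1 differed by -0.39 and 0 were lower. XRCC4, TP63 and CHEK1 were lowest in BCB-negative oocyte 3, at 3.19, 2.72 and 7.62 FPKM. The other BCB-negative oocytes had 10.8 and 9.89, 6.21 and 7.27, and 15.85 and 15.19 FPKM. Part of each difference therefore came from BCB-negative oocyte 3. The median of the list was 0.27 at percentile 94.0, and 0.09 without BCB-positive oocyte 3. Of 17 apoptosis genes, 2 were higher, DIABLO by 0.98 and TP63, and 0 lower. Their median was 0.01 at percentile 25.3. Of 27 genes of autophagy and the lysosome, 1 was higher and 1 lower. TSC2, an inhibitor of growth signalling, differed by 0.64 and MAP1LC3A, of the autophagosome membrane, by -0.69. ATG14 and WIPI2 differed by 0.48 and -0.41, and by 0.34 and -0.26 without BCB-positive oocyte 3, and the median was 0.10 at percentile 54.2. It was 0.02 at percentile 38.9 without that oocyte, and 0.02 without BCB-negative oocyte 3.

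The medians of the heat shock and paracrine receptor lists stayed high among matched random lists when BCB-positive oocyte 3 was left out, but 0 heat shock genes then met the rule. Of 26 genes of the heat shock and unfolded protein response, 1 was ordered and at least 1.5-fold higher and 0 lower. The chaperone HSPH1 was at 34.6, 27.9 and 31.3 FPKM in BCB-negative and at 42.4, 45.9 and 93.03 FPKM in BCB-positive oocytes. DNAJA1 and PDIA4 differed by 0.54 and 0.37. HSPH1 differed by 0.84 with BCB-positive oocyte 3 and 0.49 without it, where DNAJA1 differed by 0.21. The list score of BCB-positive oocyte 1, -0.16, lay among those of the BCB-negative oocytes, -0.26 to -0.08. The list's median was 0.33 at percentile 99.2 with that oocyte and 0.24, again at percentile 99.2, without it. Of 18 genes of gap junctions, adhesion and paracrine receptors, 2 were higher and 0 lower, and the 2 kept the rule without that oocyte. Chance orders 0.9 of 18 genes each way at any size. TGFBR2, a receptor of TGF-beta, was at 0.13, 0 and 2.42 FPKM in BCB-negative and at 2.69, 4.14 and 5.96 FPKM in BCB-positive oocytes. KIT averaged 3.58 and 7.66 FPKM, and CTNNB1, beta-catenin, differed by 0.37. The median was 0.43 at percentile 96.6, and 0.39 at percentile 98.4 without that oocyte. It was 0.27 without BCB-negative oocyte 3, whose list score of -0.29 lay below the -0.01 and 0.05 of the other BCB-negative oocytes.

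Among 5523 transcripts of 1956 genes, 403 had an ordered share of their gene, or 7.30%. Chance orders 10% of untied values, which is no yardstick here, since shares tied at 0% or 100% cannot be ordered and transcripts of a gene mirror each other. Of these, 107 transcripts in 69 genes were at least 20 percentage points apart. In PAPOLA, poly(A) polymerase alpha, the transcript of 4418 bases took 87.4%, 77.8% and 75.3% of the gene in BCB-negative oocytes and 19.9%, 0% and 0% in BCB-positive oocytes. The PAPOLA transcript of 4493 bases took 0%, 9.02% and 0%, and 64.6%, 94.4% and 65.3%. In MGRN1, a ubiquitin ligase, the transcript of 2595 bases averaged 95.1% and 28.8%. Transcripts of PES1, of ribosome biogenesis, and FAM136A shifted by -64.6 and -64.4 percentage points, and a transcript of gene 100154430 by -69.4. That of PES1 took 15.9%, 100% and 100% in BCB-negative oocytes and 0%, 7.81% and 14.3% in BCB-positive oocytes. That of FAM136A took 100% in each BCB-negative oocyte and 79.8%, 5.42% and 21.6% in BCB-positive oocytes. These shares rest on reads divided between models of similar length.

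A few markers of other cells were present in every oocyte. Of 25 cumulus and granulosa markers, 14 were found, and they summed to between 35.8 and 56.9 FPKM in an oocyte. Most of this came from INHBA and FST, with means of 25.9 and 13.1 FPKM, and their log2 differences were 0.30 and -0.15 with the classes overlapping. Named after their values were seen, HSD17B1 and STAR of this list were higher in every BCB-positive oocyte. HSD17B1 was at 0.15, 1.31 and 0.16 FPKM against 2.25, 1.64 and 1.78 FPKM, and STAR at 0.05, 0.37 and 0.16 FPKM against 1.56, 1.79 and 0.40 FPKM. STAR was narrowly ordered, and its mean of 0.72 FPKM lay below the limit of 1 FPKM for compared genes. Chance orders 10% of genes in either direction, so nothing on cumulus cells was concluded from these picks. Of 12 theca and stroma markers, 10 were found, summing to between 28.8 and 62.3 FPKM, led by TAGLN at 25.5 to 57.9 FPKM, with DCN at most 3.33 FPKM. PTCH1 of this list, also named after its values were seen, went the other way. It was at 1, 0.86 and 1.72 FPKM in BCB-negative and at 0.50, 0.43 and 0.75 FPKM in BCB-positive oocytes. Only 3 of 8 endothelial markers were found, summing to between 6.94 and 23.0 FPKM, highest in BCB-positive oocyte 3, led by TEK at 6.90 to 20.4 FPKM, with PECAM1 at most 3.76 FPKM. Leukocyte markers, 8 of 14 found, summed to between 7.53 and 17.6 FPKM, also highest in that oocyte. CD2 overlapped between classes, and CD3E averaged 0.73 FPKM in BCB-negative and 3.84 FPKM in BCB-positive oocytes. Of 9 erythroid markers only AHSP was found, in BCB-positive oocyte 3 at 0.44 FPKM. The most abundant transcripts of the oocytes were DNAJC15, FTL, DYNLL1, the zona pellucida glycoprotein ZP3 and the ubiquitin gene UBB. FTL, ferritin light chain, was ordered, with means of 35607 FPKM in BCB-negative and 24838 FPKM in BCB-positive oocytes, a log2 difference of -0.54, and -0.33 without BCB-positive oocyte 3. DNAJC15, DYNLL1, ZP3 and UBB differed by -0.71, -0.69, -0.69 and 0.25 and overlapped between classes. Without that oocyte they differed by -0.24, 0.01, -0.42 and 0.32, so much of the DNAJC15 and DYNLL1 differences came from that library.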

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

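The sum of PYURF and PIGY and the removal of a length trend, which also removed each oocyte's overall level, were chosen after seeing the data. No paired analysis was possible because the comparison comes from no test and the oocyte numbers only name oocytes. Leaving out each oocyte in turn gave 360 to 861 higher and 237 to 321 lower genes, since fewer oocytes are easier to order, and 203 to 260 isoforms. A minimum of 5 FPKM gave 169 and 57 genes, with fewer genes compared. Isoforms numbered 189 at a gene total of 1 FPKM and 37 at 20 FPKM. The PYURF difference turned to 0.31 as the sum with PIGY. Leaving out oocytes in turn moved list medians over -0.587 to 0.0051 for ribosomal proteins and -0.06 to 0.48 for the spindle, both turned without BCB-positive oocyte 3. Ranges were -0.159 to 0.027 for the pentose phosphate pathway, -0.013 to 0.214 for glycolysis, -0.067 to 0.094 for antioxidant genes, -0.171 to -0.029 for maternal-effect genes, 0.019 to 0.179 for chromatin modifiers, 0.184 to 0.366 for histones, -0.043 to 0.292 for apoptosis, 0.062 to 0.268 for lipid genes, 0.107 to 0.374 for oocyte identity, 0.274 to 0.529 for receptors, 0.018 to 0.181 for autophagy and 0.239 to 0.497 for heat shock. They were -0.422 to -0.034 for the respiratory chain, 0.022 to 0.328 for mitochondrial maintenance, 0.032 to 0.353 for meiosis, 0.020 to 0.464 for the proteasome, 0.086 to 0.277 for mRNA storage and 0.087 to 0.459 for DNA repair. Size factors gave -0.056 for antioxidant genes, -0.282 for maternal-effect genes, 0.045 for chromatin modifiers and 0.075 for histones. They also gave 0.055 for glycolysis, 0.155 for mitochondrial maintenance, 0.116 for oocyte identity, 0.145 for meiosis and 0.162 for mRNA storage. Removing the length trend gave -0.057 for antioxidant genes, -0.315 for maternal-effect genes, -0.036 for chromatin modifiers and -0.021 for autophagy. It also moved meiosis to 0.099, mRNA storage to 0.100, mitochondrial maintenance to 0.105, oocyte identity to 0.090, the spindle to 0.210, DNA repair to 0.159, glycolysis to 0.066 and the pentose phosphate pathway to -0.118. No filter gave 0.00046 for maternal-effect genes. It also gave 0.041 for mitochondrial maintenance, 0.125 for meiosis, 0.082 for glycolysis, 0.146 for mRNA storage and 0.024 for antioxidant genes. A minimum of 5 FPKM gave 0.268 for receptors and 0.235 for autophagy. A pseudocount of 0.1 FPKM gave -0.035 for autophagy. The ratio of class means gave 0.216 for autophagy. The within minus between class correlation, 0.002 with all oocytes, turned in 4 of the 6 omissions, with a range of -0.0064 to 0.017. The cause of the other shifts was not tested. Of 98 named differences, 16 moved by more than the SD between oocytes with a pseudocount of 0.1 FPKM. Depth limits the least abundant genes, since 3 counts were worth 0.325 to 0.421 CPM in an oocyte.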

Other observations

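The tests on cumulus and granulosa cells, on PYURF with PIGY and on PAPOLA were chosen only after the result was seen, as were the genes named for BCB-positive oocyte 3. Removal of a length trend was also chosen after seeing the data. The bound for the ribosomal list was written before its value without that trend was seen, and a condition on its spread between oocytes was added after. That oocyte carried LDHA, lactate dehydrogenase, at 692 FPKM, against 29.8 to 62.8 FPKM in the other oocytes. SLC31A2, a copper transporter, stood at 169 FPKM against 19.8 to 30.6, RARS, arginyl-tRNA synthetase, at 159 against 18.6 to 34.3, and the splicing factor PRPF3 at 85.5 against 7.55 to 17.9. DNM1L, the GTPase of mitochondrial fission, stood at 31.3 FPKM against 0 to 3.80. The ribosomal protein transcript RPS7 stood at 338 FPKM against 1617 to 1956, RPLP1 at 1251 against 5502 to 7349, and DYNLL1, a dynein light chain, at 7254 against 28163 to 34783. At least 2-fold above all other oocytes were 760 genes in this oocyte and 48 to 97 genes in each of the rest. At least 2-fold below all others were 285 genes in it and 64 to 230 in each of the rest.

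BCB-positive oocyte 3 also had the deepest library, and longer genes were higher in it, with a slope of 0.12 on log2 length against -0.05 to 0.01 in the others. Greater depth was argued against, since after thinning every library to the same total its mean correlation with the others was 0.874, below the 0.905 of the next lowest. A bias with gene length was argued against as the whole cause, since after the length trend was removed its correlation was 0.878. The ribosomal list in this oocyte had a median of -0.76 before and -0.63 after removal, where the others lay at -0.06 to 0.19 (SD 0.10), so the trend was argued against as its whole cause. The difference between the classes was -0.31 before and -0.30 after, but removal also took out each oocyte's overall level. Cumulus or granulosa cells were argued against as the cause of the lower ribosomal list. RNA from such cells that lowered it would lower genes of oocyte identity at least as far. In this oocyte the oocyte identity list had a median of 0.49 (SD over members 0.93) against the mean of the other oocytes, and the ribosomal list -0.91. For the rest of the pattern such cells stay open. Their markers summed to 44.6 FPKM, within the 35.8 to 56.9 FPKM of the other oocytes, but most of the sum was INHBA and FST, whose level in every oocyte would hide a small share. No biological explanation was tested.

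The PYURF difference may come from how reads were divided between PYURF and PIGY, which overlap. PYURF held 226 and 245 FPKM in BCB-negative oocytes 1 and 2 and PIGY held 252 FPKM in BCB-negative oocyte 3 and 309, 401 and 222 FPKM in the BCB-positive oocytes. Their sum ran from 222 to 401 FPKM, differed by 0.31 on the log2 scale and was not ordered. The division did not fully follow BCB class, since BCB-negative oocyte 3, with PYURF at 0.46 FPKM, stood with the BCB-positive oocytes. A true switch between PYURF and PIGY would leave the sum as steady, so a link in part to BCB class stays open and untested.

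For PAPOLA, a real switch and reads split between similar transcript models cannot be told apart. The summed share of the transcripts that swap differed by -1.76 percentage points, but either explanation keeps that sum, so the test could not have decided.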
